A study of Mus musculus with 4 samples.

How the data were processed

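The series holds 4 single-colour arrays hybridised with biotin-labelled total RNA of mouse bone marrow, 2 from mice with MN1 leukemia and 2 from Gr1-positive and CD11b-positive cells of healthy mice. The RNA was extracted with Trizol and its quality was read on a Bioanalyzer, per the labels' protocols. The design text describes the arrays of each group as biological replicates. The deposited values are MAS5 signals, linear intensities that the authors made with GCOS 1.3.0, per the submitters' processing notes. The scale target, the settings and the detection calls are not given in the sources used here. In the deposited table the mean signal after trimming 2% at each end was 500.003 in both leukemic and 500.004 in both mature arrays, so each array had been scaled to 1 target before deposit. The median signals were 85.4 and 80.9 in the leukemic and 59.1 and 74.8 in the mature arrays. MAS5 subtracts a mismatch-based background and scales each array linearly, which leaves dim probe sets noisy and lets the composition of the RNA move all other signals.

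The table held 45101 probe sets, of which 64 were controls of the manufacturer and were left out of the tests. Gene symbols came from the platform annotation, which can be old. Of the other 45037 probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none here. The gene ID of 34754 probe sets was found in a RefSeq gene table of assembly GRCm38.p6, which was used for names and for the X and Y chromosomes alone, and 0 symbols changed. No gene was named from a probe set with several symbols. Every column of the table belonged to a sample of the series.

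The signals were taken as log2(signal + 16) with no further scaling. The 40% of probe sets with the lowest mean signal over the 4 arrays were left out, which put the lowest kept mean signal at 47.6 and kept 27022 probe sets. Each gene was read from its probe set with the highest mean signal, which left 12378 genes, 5727 of them with several kept probe sets. Another 4617 kept probe sets named no single gene. Leukemic and mature arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The fit had 2 residual degrees of freedom, 6.90 after moderation, and the median SE of a log2 fold change was 0.33. For the whole array, the correlation across genes was 0.962 between leukemic replicates, 0.949 between mature replicates and 0.846 to 0.878 between arrays of different groups. Genes are not independent replicates, so no p is given for these correlations.

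Gene lists of cell types, pathways and the HOX complex were fixed before the data were examined, from textbook knowledge, and 27 of them had at least 3 tested members. Each list was tested with camera at a preset correlation of 0.01 with Benjamini-Hochberg adjustment over lists, again with an estimated correlation, and with fry. Counts adjusted over the list alone are given where they differ from those over all genes, and for the HOX complex. The sex-linked genes and the 3′ to 5′ ratios of the control probe sets served as checks. The named genes followed a rule fixed at the same time. It took Mn1 and the antigens of the gate, the 10 largest changes in each direction among genes whose arrays do not overlap between groups, all tested MEIS, PBX and abdB-like HOX genes, and in each other list up to 3 called members in the main direction and 1 in the other. Unannotated symbols were passed over, and no named gene had probe sets called in opposite directions. Later gene lists, named in the closing section, were added after the data had been seen. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

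The alternatives fixed before the data were examined were pseudocounts of 1 and 64, no filter on low signals, the lowest 60% left out, quantile normalization, every array at the same median, the mean of a gene's probe sets, and no probe sets that can match several transcripts (suffixes _x_at, _s_at and _a_at). Further ones were variance models without a trend and with a robust trend, a replicate block, a minimum of 2-fold, each probe set tested, and each array left out in turn. Where an array was left out, the lone array of its group was assumed to vary like the other group. Scaling to the hybridization controls, leaving out X and Y genes and leaving out the 3 granulocyte lists were added after the data had been seen. The scaling to these controls is left out of the ranges of adjusted p, because its degrees of freedom after moderation came to 24756 and its SEs rose, so its p values are not comparable with the others. The same scaling with the mean factor of each group, also added later, was run for the count of changed genes and for Pbx2 and the named genes whose calls were lost under that scaling. Its log2 fold changes are kept. Both groups use the replicate numbers 1 and 2, but nothing in the labels says that a number pairs arrays. The replicate block stays in the ranges of adjusted p. It had 14.6 degrees of freedom after moderation, against 6.90 in the main analysis, so low ends of these ranges can rest on it.

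The fit was tested on simulated data with 12378 genes in 20 runs, with known log2 changes of 1, 2 and 3. With 200 changed genes and spreads drawn from the moderated SDs, 15.8%, 79.9% and 89.3% were recovered, with a mean of 10.8 false calls. With 5375 changed genes, 62.0%, 95.8% and 99.7% were recovered, with a mean of 129 false calls. With spreads drawn from the unmoderated SDs, which was the setting tried at the start, 0%, 4.48% and 21.4% of 200 and 53.2%, 84.3% and 93.1% of 5375 changed genes were recovered. The moderated spreads were added after that low recovery had been seen, because SDs from 2 degrees of freedom scatter more widely than true ones. With no changed genes, the mean number of calls was at most 0.45 in each setting. Lists were tested in 1 further simulated data set, with 1 list shifted by 1 on the log2 scale. There camera called 1 list with the preset and 0 with an estimated correlation. The simulated genes varied independently, while the estimated correlation was 0.92 for the secondary and tertiary granule genes. The simulation thus does not test false calls among correlated genes. Published progenitor profiles were not used here, and the number of arrays, not a read depth, limits the precision.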

Results

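The study set bone marrow cells from mice with leukemia driven by MN1 against mature myeloid bone marrow cells from healthy mice. MN1 is a transcriptional coregulator that is overexpressed in part of human acute myeloid leukemia. It had been introduced by a retrovirus into marrow of C57BL/6J mice taken 4 days after 150 mg/kg fluorouracil and cultured for 48 hours, and the sorted cells were then transplanted into irradiated recipients. The mature cells were positive for Gr1 and CD11b, surface antigens of granulocytes and monocytes. Choosing cells by these antigens can itself raise granulocyte and monocyte genes, and lower genes of other lineages, in the mature group. No normal immature cells are among the 4 arrays, so MN1 leukemia and stage of maturity cannot be told apart. Each group had 2 arrays from separate biological replicates, and the number of arrays limits the precision of every value. Expression was read as MAS5 signal, a linear intensity, at 45101 probe sets, and 12378 genes were tested. A log2 fold change is leukemic minus mature on the log2(signal + 16) scale, which understates the change of dim genes, and ± is the SD (n = 2). The series title names the complex of MEIS1 and abdB-like HOX proteins as the subject, so these genes were compared first. Each range of an adjusted p over alternatives leaves out scaling to the hybridization controls, for a reason given with that scaling below. It keeps the replicate block, which had 14.6 degrees of freedom after moderation against 6.90 in the main analysis. The low end of a range can rest on that block and then overstates the support. The published common and granulocyte-macrophage progenitor profiles that the study also used were not analysed here.

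The single probe set naming Mn1 read 17.7 and 92.6 in the leukemic arrays and 3.92 and 12.1 in the mature arrays. Its mean lay below the filter on low signals, so it was not tested, and whether its probes see the introduced sequence is not given in the sources used here. Itgam, which encodes CD11b, was lower in leukemic marrow, with a log2 fold change of -3.31 (SE 0.33) and signals of 445 ± 197 against 4348 ± 84.1 (limma adjusted p = 7.0e-04). Of the Gr1 antigens, Ly6g had no probe set naming it here, and a probe set shared by Ly6c1 and Ly6c2, which names no single gene, read 13319 and 5559.7 in the leukemic arrays and 35135 and 28832 in the mature arrays.

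Of the MEIS, PBX and abdB-like HOX genes bright enough to be tested, some differed between the groups and others did not pass. Hoxa9 gave a signal of 12349.8 ± 2396 in leukemic and 50.2 ± 42.0 in mature marrow, a log2 fold change of 7.69 (SE 0.46). Its other, dimmer probe set gave 3.64 (SE 0.36). Hoxa10 was higher by 6.14 (SE 0.30), Hoxa11 by 3.85 (SE 0.37), Meis2 by 6.80 (SE 0.28) and Meis1, the HOX partner that the title names, by 2.75 (SE 0.44). The abdB-like HOX genes are the homeobox genes at the 5′ end of the HOX clusters, and MEIS and PBX proteins bind DNA together with HOX proteins. Of the 25 listed members of both groups, 12 were tested and 7 passed, 6 of them higher and 1 lower in leukemic marrow, and the counts adjusted over the list alone were the same. The lists follow the complex that the study chose, so the counts are not independent evidence of its direction.

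Among the tested cofactors, Meis1 read 531 ± 22.3 against 71.3 ± 44.4 (adjusted p = 0.0031). All 3 of its probe sets were higher in both leukemic arrays than in either mature array. The dimmest of them did not pass when each probe set was tested (1.17, adjusted p = 0.087). Meis2 read 4834 ± 850.4 against 27.2 ± 3.19 (adjusted p = 1.1e-04). Pbx4 was higher by 2.95 (SE 0.54), from a dim signal of 4.45 ± 0.32 to 143 ± 24.2 (adjusted p = 0.0052), and Pbx2 was lower, with -1.23 (SE 0.24, adjusted p = 0.0067). Without leukemic replicate 2 the adjusted p was 0.054 for both Pbx4 and Pbx2, and without leukemic replicate 1 it was 0.067 for Pbx2 (range over alternatives 0.0035 to 0.054 for Pbx4 and 0.0035 to 0.067 for Pbx2). Pbx3 (0.83, adjusted p = 0.088), Meis3 (0.16, 0.80), Pknox1 (-0.50, 0.23) and Pknox2 (-0.57, 0.31) did not pass. As a list, the MEIS and PBX cofactors had a median of 0.50 and no call (camera adjusted p = 0.58; range over alternatives 0.39 to 0.77), while fry passed it as higher (adjusted p = 0.014). Its median turned to -0.69 with arrays scaled to the hybridization controls.

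Among the abdB-like genes, the adjusted p was 1.5e-04 for Hoxa9, 1.1e-04 for Hoxa10 and 6.4e-04 for Hoxa11. The signals were 2501 ± 47.6 against 19.6 ± 2.90 for Hoxa10 and 1006 ± 146 against 56.7 ± 25.4 for Hoxa11. A second, dimmer probe set of Hoxa10, which is the one used when probe sets that can match several transcripts are left out, gave 1.16 (adjusted p = 0.12; range over alternatives 2.7e-08 to 0.12). Hoxd13 did not pass (-0.71, adjusted p = 0.34). With 4 tested members, the abdB-like list was called higher, with a median of 5.00 (camera adjusted p = 0.030; adjusted p = 0.33 with an estimated correlation). The filter kept genes by their mean signal over all arrays, so a gene bright in leukemic marrow alone could enter. Without the filter the list's median fell to 0.11 and the call was lost (adjusted p = 0.33). It was also lost when probe sets that can match several transcripts were left out, with a median of 2.51 (adjusted p = 0.13), and without mature replicate 1 (adjusted p = 0.052; range over alternatives 0.0067 to 0.33). The members left untested were dim in both groups. The highest mean signals among them were those of Hoxa13, 29.6 ± 25.5 in leukemic and 60.1 ± 10.2 in mature marrow, and of Hoxd9, 25.9 ± 23.3 and 37.6 ± 28.3. Hoxc9 read 27.2 ± 6.19 and 14.6 ± 1.55, Hoxc10 17.4 ± 7.95 and 19.0 ± 2.44, and Hoxd11 15.2 ± 19.2 and 4.90 ± 1.16. Hoxc13 read 12.8 ± 9.40 and 9.87 ± 1.40, and Hoxd12 12.2 ± 7.48 and 5.88 ± 2.80. Hoxb9 at 8.58 ± 1.06 and 9.78 ± 1.17, Hoxb13 at 6.75 ± 2.32 and 5.14 ± 1.79 and Hoxd10 at 6.34 ± 5.33 and 7.41 ± 2.62 were near the bottom of the scale. Hoxc11 and Hoxc12 had no probe set naming them here.

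**Figure D1:**
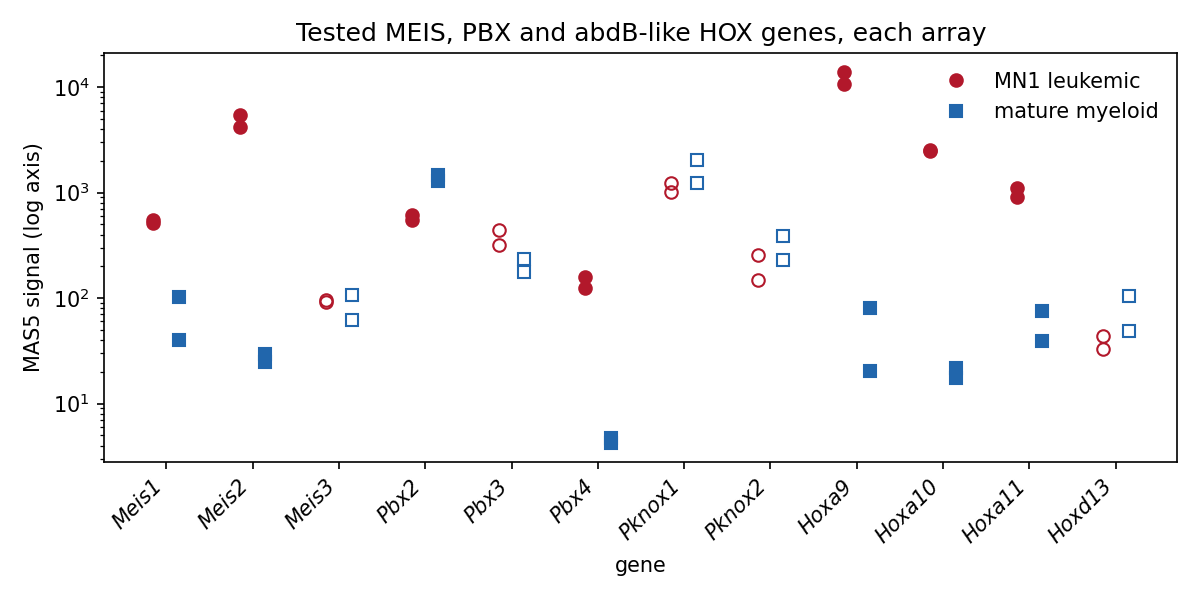
MAS5 signal (log axis) of each tested MEIS, PBX and abdB-like HOX gene in each array, with leukemic arrays as circles, mature arrays as squares, and filled symbols for genes that passed. Hoxa9, Hoxa10, Hoxa11, Meis1, Meis2 and Pbx4 lie higher in both leukemic arrays, Pbx2 lies lower, and the 5 genes with open symbols did not pass.

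Other HOX genes did not move one way. Of 8 tested members, Hoxa5 was higher (4.94, adjusted p = 7.7e-04), Hoxb4 (-1.53, adjusted p = 0.020) and Hoxb1 (-1.89, adjusted p = 0.049) were lower, and adjusted over the list alone 3 were lower. The Hoxb1 call was lost whichever array was left out (-2.31 to -1.47). It was also lost with a pseudocount of 1 (adjusted p = 0.071), the mean of its probe sets (0.051) and a replicate block (0.071). Leaving out probe sets that can match several transcripts lost it too (0.051). The Hoxb4 call was lost without leukemic replicate 1 (-1.67), leukemic replicate 2 (-1.38) or mature replicate 1 (-1.44). The list was not called, its median was 0.78 while its test pointed down, and the median was -0.26 with arrays scaled to the hybridization controls. Genes linked to HOX and MEIS1 leukemia included 13 higher and 5 lower members of 22 tested, with a median of 2.20 (camera adjusted p = 0.016; adjusted p = 0.33 with an estimated correlation). Cd34 rose by 6.38 (SE 0.72), Sox4 by 6.20 (SE 0.30) and the RNA-binding protein gene Msi2 by 5.53 (SE 0.31), while the pseudokinase gene Trib1 fell, with -3.79 (SE 0.47). With the mean of a gene's probe sets Msi2 was at 3.19 and Hoxa5 at 3.25. That list's call was lost when probe sets that can match several transcripts were left out (adjusted p = 0.13; range over alternatives 0.0018 to 0.13).

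Beyond the HOX genes, camera with the preset correlation called stem cell, erythroid and ribosome biogenesis genes higher and neutrophil, monocyte and inflammatory genes lower in leukemic marrow. With an estimated correlation none of these lists passed (adjusted p = 0.33 to 0.35). That test also called 0 lists in the simulation with 1 list shifted, so its lack of calls here decides nothing. Of 12378 genes, 5375 changed (limma, Benjamini-Hochberg adjusted p threshold 0.05), 3403 higher and 1972 lower, so that 63.3% were higher, and 562 rose and 199 fell at least 8-fold. In every changed gene both arrays of one group lay beyond both arrays of the other. With 2 arrays a group, a gene with overlapping arrays could not pass the threshold here, so this adds no evidence. The split depended on the scaling, since the median log2 fold change over all tested genes was 0.28. With every array at the same median it was 2342 higher and 2528 lower (48.1% higher). With arrays scaled to the hybridization controls, an alternative chosen after the data were seen, it was 1096 higher and 5643 lower (16.3% higher), and the median over all genes moved to -0.95. Of all tested genes, 59.5% lay above 0 in the main analysis and 22.9% under that scaling. It puts a common log2 offset of 0.41 between the leukemic replicates, and limma then pooled the spread of all genes (24756 degrees of freedom after moderation, against 6.90 in the main analysis). With the mean factor of each group in place of each array's own, which removes that offset, there were 6.68 degrees of freedom, and with the offsets between replicates alone 24756. The offset also raised the median SE to 0.45, from 0.33 with group factors, so the adjusted p was smaller for some genes (Pbx2 2.6e-08 against 3.2e-04) and larger for others (Chaf1b 0.13 against 0.043), and its calls are not comparable with the others. With group factors, also chosen after the data were seen, 1083 genes were higher and 5944 lower. Without leukemic replicate 1 the count of changed genes was 3429, and without leukemic replicate 2 it was 2575.

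The RNA and hybridization controls also differed between the groups. The 3′ to 5′ signal ratio of beta-actin was 3.28 and 3.09 in the leukemic arrays and 1.32 and 1.39 in the mature arrays, and that of Gapdh was 3.94 and 3.68 against 1.82 and 2.18. The geometric mean signal of the 18 hybridization control probe sets was 11918 and 8949.8 against 4044 and 4168. With 2 arrays a group, an exact two-sided permutation test can give no p below 0.33, and no parametric test was run on these measures. Among sex-linked genes, Xist, which is transcribed from the inactive X chromosome of females, read 14512, 19642 and 7138 in the leukemic arrays and mature replicate 1, and 114 in mature replicate 2. The Y-linked gene Eif2s3y read 3.01, 2.51 and 2.90 in the same 3 arrays and 4409 in mature replicate 2. The probe sets with the highest mean signal read 17.0, 28.7 and 1.77 against 599 for Kdm5d and 22.6, 32.7 and 45.6 against 127 for Uty, in the same order. Ddx3y had no probe set naming it here. Without genes on the X and Y chromosomes, 5237 genes changed.

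**Figure D2:**
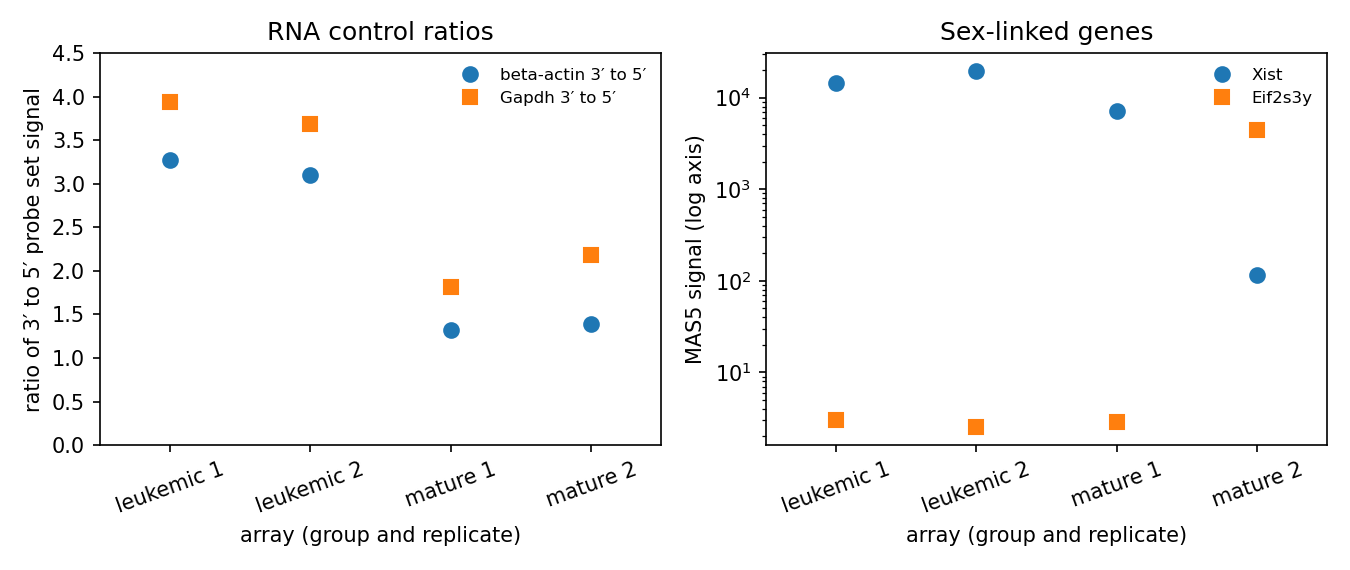
The left panel plots the ratio of 3′ to 5′ control signal of beta-actin and Gapdh (no unit) in each of the 4 arrays, and the right panel the MAS5 signal (log axis) of Xist and Eif2s3y. Both ratios are higher in the leukemic arrays, with beta-actin at 3.28 and 3.09 against 1.32 and 1.39, and mature replicate 2 alone has a low Xist signal and a high Eif2s3y signal.

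On the scale with a pseudocount of 16, the largest increases were those of the germ line RNA helicase gene Ddx4 (8.96, SE 0.44), the thrombin receptor gene F2r (8.73, SE 0.23), the mast cell protease gene Cpa3 (8.56, SE 0.56), Bex1 (8.37, SE 0.53) and the carbonic anhydrase gene Car1 (8.31, SE 0.27). F2r read 33062 ± 4011 in leukemic and 61.4 ± 4.29 in mature marrow, and Ddx4 15048 ± 2208 and 17.4 ± 20.4. The fatty acid binding protein gene Fabp7 (8.09), the MYC family gene Mycn (8.07), the septin gene Septin8 (7.74), Clca3a1 (7.74) and Hoxa9 followed. The adjusted p of these 10 genes lay between 3.6e-05 and 3.6e-04. Their order rests on dim mature signals and depends on the pseudocount. With a pseudocount of 1, Fabp7 (9.99), Bex1 (9.84), Cpa3 (9.38), Septin8 (9.33) and Clca3a1 (9.25) lay above F2r (9.04) and Car1 (8.61).

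On the same scale, the largest decreases were those of the immunoglobulin A heavy chain gene Igha (-6.58, SE 0.74), the histamine-degrading enzyme gene Hnmt (-6.48, SE 0.36), the semaphorin gene Sema4f (-6.45, SE 0.34), the cyclooxygenase gene Ptgs2 (-6.44, SE 0.38) and the lipid hydrolase gene Pla2g7 (-6.01, SE 0.30). Hnmt read 3.54 ± 3.40 in leukemic and 1719 ± 176 in mature marrow. Igha had a wide spread in mature marrow, at 3414 ± 3381, against 9.68 ± 1.54 in leukemic marrow. The immediate early transcription factor gene Fos (-5.37), Marcks (-5.21), S100a4 (-5.13) and the chemokine genes Ccl6 (-5.06) and Cxcl2 (-5.05) completed the 10, with an adjusted p between 1.1e-04 and 0.0010. With a pseudocount of 1, Hnmt (-8.80), Ptgs2 (-8.72) and Sema4f (-8.05) fell further than Igha (-7.84), so this order depends on the pseudocount as well. In these sets of 10, 1 gene with an unannotated symbol was passed over.

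Markers of stem and progenitor cells rose together, with 18 of 21 tested members higher, none lower and a median of 2.96 (camera adjusted p = 5.9e-08; adjusted p = 0.33 with an estimated correlation). Mycn rose from 47.1 ± 13.6 to 17096 ± 4434, the adhesion receptor gene Adgrg1 from 22.8 ± 13.9 to 3854 ± 225 (6.69, SE 0.34), and Cd34, which encodes a surface antigen of early progenitors, from 55.2 ± 68.6 to 4439 ± 1386. Mycn was read from its brightest probe set, while its others gave 4.16 (adjusted p = 0.0012) and -0.09 (0.92), and the mean of its probe sets 4.05. Leukemic replicate 1 was below leukemic replicate 2 in 18 of the 21 genes. The median log2 difference was -0.31, replicate 1 minus replicate 2. Against mature cells alone, a rise of these markers does not separate MN1 leukemia from immaturity.

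Granulocyte genes were lower in leukemic marrow, a direction that the choice of the mature cells by Gr1 and CD11b itself favours. In the mature neutrophil list 27 of 30 tested genes fell and 1 rose, with a median of -2.56 (camera adjusted p = 1.8e-14; adjusted p = 0.33 with an estimated correlation). Ptgs2 fell from 1668 ± 477 to 3.08 ± 1.82, Ccl6 from 15953 ± 2877 to 480.0 ± 199 and Cxcl2 from 5177 ± 254 to 143 ± 41.7, while the stefin gene Stfa3 rose by 4.36 (SE 0.38). Among secondary and tertiary granule genes 14 of 21 fell and none rose, with a median of -1.62 (camera adjusted p = 2.5e-06; adjusted p = 0.48 with an estimated correlation). The arginase gene Arg2 fell, with -3.83 (SE 0.36), as did Pglyrp1, with -2.98 (SE 0.42), and the metalloprotease gene Adam8, with -2.94 (SE 0.40). All 6 tested NADPH oxidase genes, whose products make the oxidative burst, fell, with a median of -2.12 (camera adjusted p = 3.1e-04; adjusted p = 0.37 with an estimated correlation), among them Ncf4 (-2.89), Cybb (-2.79) and Ncf1 (-2.49).

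Primary granule genes, which are made earlier in granulocyte development, were lower in 4 and higher in 2 of 19 cases, with a median of -0.45 (camera adjusted p = 0.036; adjusted p = 0.67 with an estimated correlation). Fcnb (-4.07, SE 0.44), the hexokinase gene Hk3 (-2.50, SE 0.41) and Serpinb1a (-1.50, SE 0.38) fell, and the cystatin gene Cst7 (2.03, SE 0.31) rose, a call lost with arrays scaled to the hybridization controls (adjusted p = 0.13, and 0.088 with group factors; range over alternatives 8.2e-05 to 0.021). The list's call was lost without leukemic replicate 2 (adjusted p = 0.40), without mature replicate 1 (0.19), with quantile normalization (0.060) and with every array at the same median (0.054), with a range over alternatives of 1.3e-04 to 0.40. The call of Serpinb1a was lost without leukemic replicate 2 (adjusted p = 0.086; range 0.0013 to 0.086). The leukemic arrays differed from each other in all of these lists. Leukemic replicate 1 was higher than leukemic replicate 2 in 19 of 19 primary granule genes (median log2 difference 1.12) and 21 of 21 secondary and tertiary granule genes (1.20). It was higher in 25 of 30 mature neutrophil genes (0.88) and 6 of 6 NADPH oxidase genes (1.09). The mature arrays differed by a median of 0.42 in the primary granule genes. Without the genes of the 3 granulocyte lists, which left 12308 of 12378 genes, 5361 changed. Few genes were removed, so this count says little about granulocyte content.

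Monocyte and macrophage genes and a list of myeloid transcription factors, which includes immediate early genes such as Fos, were also lower. Of 22 monocyte and macrophage markers 16 fell and 2 rose, with a median of -2.00 (camera adjusted p = 3.0e-07; adjusted p = 0.33 with an estimated correlation). Klf4 fell, with -4.58 (SE 0.37), the fibronectin gene Fn1 with -4.19 (SE 0.48) and the Fc receptor gene Fcgr1 with -3.12 (SE 0.60), and the scavenger receptor gene Cd163 rose by 2.32 (SE 0.45). The Cd163 call was lost with arrays scaled to the hybridization controls (1.18, adjusted p = 0.060, and 0.065 with group factors). Of 26 myeloid transcription factors 15 fell, 16 when adjusted over the list alone, and 2 rose, with a median of -1.92 (camera adjusted p = 1.2e-06; adjusted p = 0.33 with an estimated correlation). Fos fell from 31077 ± 5245 to 733 ± 54.3 and Klf2 from 9508 ± 3423 to 583 ± 139, while Runx3 rose by 1.63 (SE 0.34). Without leukemic replicate 2 the adjusted p was 0.080 for Cd163 (range over alternatives 0.0011 to 0.080) and 0.12 for Runx3 (range 0.0037 to 0.20), and Runx3 was at 0.95 (adjusted p = 0.20) with the mean of its probe sets and at 0.39 with arrays scaled to the hybridization controls.

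Genes of toll-like receptor and inflammatory signalling fell in 20 of 28 cases and rose in 1, with a median of -1.90 (camera adjusted p = 1.4e-09; adjusted p = 0.33 with an estimated correlation). Besides Ptgs2 and Cxcl2, the cytokine gene Il1b fell, with -4.25 (SE 0.39), and Il6 rose by 3.76 (SE 0.61). Interferon-stimulated genes fell in 8 of 23 cases, with a median of -0.68 (camera adjusted p = 9.2e-05; adjusted p = 0.44 with an estimated correlation). The replicates differed by amounts near that shift, with a median of replicate 1 minus replicate 2 of 0.74 in mature and -0.39 in leukemic marrow, where replicate 1 was higher in 5 of 23 genes. Ifit3 (-2.04), Mx1 (-2.02) and Gbp2 (-2.00) led them, and the call of Mx1 was lost without either leukemic array (adjusted p = 0.053 without replicate 1 and 0.056 without replicate 2; range over alternatives 0.0013 to 0.056). Among MHC class II genes 4 of 8 fell, 5 when adjusted over the list alone, and 2 rose, with a median of -1.12 (camera adjusted p = 0.047; adjusted p = 0.33 with an estimated correlation). H2-Eb1 (-4.25, SE 0.31), H2-Aa (-4.12, SE 0.35) and the invariant chain gene Cd74 (-3.08, SE 0.36) fell and H2-Ob (4.23, SE 0.58) rose. The MHC class II call was lost without leukemic replicate 1 (adjusted p = 0.051), without mature replicate 1 (0.16), with quantile normalization (0.060), with every array at the same median (0.085), with the lowest 60% left out (0.056) and with a pseudocount of 64 (0.051). Without probe sets that can match several transcripts its median turned to 0.063 (adjusted p = 0.69). Over alternatives the list's adjusted p ran from 0.032 to 0.69.

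Erythroid markers were higher, with 12 of 15 rising, none falling and a median of 3.64 (camera adjusted p = 1.5e-05; adjusted p = 0.35 with an estimated correlation). Car1 rose from 65.6 ± 16.3 to 25838 ± 4656, the erythroid transcription factor gene Klf1 by 6.82 (SE 0.32) and Ermap by 6.54 (SE 0.38). Leukemic replicate 2 was the higher of the leukemic arrays in 14 of these 15 genes (median log2 difference -0.59, replicate 1 minus replicate 2). Mast cell, basophil and eosinophil markers rose in 5 of 10 cases, and the list was not called (median 1.44, camera adjusted p = 0.13). Among them Cpa3 rose from 40.7 ± 45.4 to 17752 ± 2532, the IgE receptor subunit gene Ms4a2 from 161 ± 25.5 to 30065 ± 6409 and the chymase gene Cma1 from 17.1 ± 1.74 to 785 ± 231. Without leukemic replicate 2 that list passed (adjusted p = 0.021; range over alternatives 0.021 to 0.35).

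Markers of the other lineages were mixed. Dendritic cell markers rose in 6 and fell in 3 of 10 cases without a call (median 2.19, camera adjusted p = 0.25; range over alternatives 0.037 to 0.37), though the list passed by fry (adjusted p = 0.030) and with the lowest 60% left out (adjusted p = 0.037). The cytokine receptor gene Flt3 (5.08, SE 0.30), Ly6d (4.81, SE 0.40) and the chemokine receptor gene Ccr9 (3.54, SE 0.38) rose and Cd209a (-2.96, SE 0.49) fell. Megakaryocyte and platelet markers rose in 4 and fell in 2 of 13 cases (median 0.81, camera adjusted p = 0.50, and a median of -0.45 with arrays scaled to the hybridization controls). The platelet glycoprotein gene Gp5 (4.23), Vwf (3.23) and the integrin gene Itga2b (3.05) rose and Clec1b (-2.98) fell. Among B cell markers 2 of 10 fell, Bank1 (-3.00) and Ighm (-2.59), and the list was not called (median -0.73, camera adjusted p = 0.091). Another probe set of Ighm gave 0.23 (adjusted p = 0.80; range over alternatives 9.3e-06 to 0.80).

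Among T and NK cell markers Bcl11b (3.02) rose and Cd3d (-3.45) fell of 8 tested (median 0.27, with the test pointing down, camera adjusted p = 0.89, and a median of -0.77 with arrays scaled to the hybridization controls). Of 7 stromal and endothelial markers 1 rose, Pdgfrb (2.69), without a call of the list (median 0.76, camera adjusted p = 0.76, and a median of -0.26 with arrays scaled to the hybridization controls). Without leukemic replicate 2 the adjusted p was 0.058 for Vwf (range over alternatives 5.9e-04 to 0.058) and 0.064 for Bcl11b (range 0.0011 to 0.064), and without leukemic replicate 1 it was 0.067 for Pdgfrb (range 0.0031 to 0.067).

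Ribosome biogenesis and DNA replication genes were higher in leukemic marrow. All 25 tested MYC and ribosome biogenesis genes rose, with a median of 3.20 (camera adjusted p = 4.2e-11; adjusted p = 0.33 with an estimated correlation). Myc itself rose by 4.60 (SE 0.27), from 159.7 ± 41.5 to 4174 ± 226, and the nucleolar protein genes Rrp9 and Nop58 by 3.86 (SE 0.35) and 3.76 (SE 0.27). S-phase and DNA replication genes rose in 23 of 30 cases, 24 when adjusted over the list alone, with a median of 1.16 (camera adjusted p = 3.1e-05; adjusted p = 0.33 with an estimated correlation), and that median was -0.14 with arrays scaled to the hybridization controls, where all genes had a median of -0.95. The origin recognition gene Orc1 (2.38, SE 0.36), the chromatin assembly gene Chaf1b (2.05, SE 0.26) and the replicative helicase gene Mcm2 (1.99, SE 0.26) led them. The calls of Chaf1b (adjusted p = 0.13; range over alternatives 1.0e-04 to 0.022) and Mcm2 (0.14; range 6.3e-05 to 0.017) were lost under that scaling, and with its group factors Chaf1b passed (0.043) and Mcm2 did not (0.065).

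Mitotic genes did not move together, with 4 of 27 higher, 1 lower, a median of 0.21 that turned to -0.11 with every array at the same median, and no call (camera adjusted p = 0.71). Adjusted over the list alone, 2 were higher and none lower. Mad2l1 (1.95), Nek2 (1.46) and Ect2 (1.21) rose and Kif23 (-0.75) fell. The calls of Ect2 (adjusted p = 0.049) and Kif23 (adjusted p = 0.037) were lost without leukemic replicate 1 (0.13 for both) and without leukemic replicate 2 (0.18 and 0.25), with ranges over alternatives of 0.0047 to 0.18 and 0.018 to 0.25. With arrays scaled to the hybridization controls, Ect2 was at -0.11 and the calls of Mad2l1 (adjusted p = 0.15; range 5.7e-05 to 0.014) and Nek2 (0.77; range 0.0012 to 0.044) were lost, as they were with its group factors (0.085 and 0.59).

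Receptors for growth factors and cytokines fell in 14 and rose in 4 of 29 cases, 15 and 5 when adjusted over the list alone, with a median of -1.14 (camera adjusted p = 2.4e-04; adjusted p = 0.33 with an estimated correlation). The macrophage colony-stimulating factor receptor gene Csf1r (-3.09, SE 0.29), Il10ra (-3.00, SE 0.41) and Il6ra (-2.95, SE 0.38) fell, and Flt3 rose from 82.1 ± 27.5 to 3254 ± 304. Another probe set of Il6ra gave 0.33 (adjusted p = 0.62), and the mean of its probe sets -1.31 (adjusted p = 0.0067; range over alternatives 5.5e-06 to 0.011). Homing and adhesion genes fell in 13 and rose in 5 of 25 cases, with a median of -1.03 (camera adjusted p = 0.0027; adjusted p = 0.33 with an estimated correlation). Besides Itgam, the tetraspanin gene Cd9 (-3.27, SE 0.33) and the chemokine receptor gene Cxcr2 (-2.65, SE 0.41) fell and the integrin gene Itga5 (1.76, SE 0.57) rose. With arrays scaled to the hybridization controls Itga5 was at 0.75 and did not pass (adjusted p = 0.32, and 0.32 with group factors). The Itga5 call was lost without leukemic replicate 1 (adjusted p = 0.066), leukemic replicate 2 (0.28) or mature replicate 1 (0.11), with a range over alternatives of 0.029 to 0.28.

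Cell cycle inhibitors and apoptosis regulators fell in 8 of 22 cases, 9 when adjusted over the list alone, and rose in 3, with a median of -0.46 (camera adjusted p = 0.011; adjusted p = 0.33 with an estimated correlation). The death receptor gene Fas (-3.81, SE 0.53), the cyclin-dependent kinase inhibitor gene Cdkn2d (-3.29, SE 0.25) and the caspase gene Casp1 (-1.72, SE 0.41) fell, and another inhibitor gene of the same family, Cdkn2b, rose from 19.3 ± 1.70 to 1599 ± 795 (5.43, SE 0.43). The list's call was lost without leukemic replicate 1 (adjusted p = 0.051; range over alternatives 0.0066 to 0.051). That of Casp1 was lost without leukemic replicate 2 (adjusted p = 0.086) or mature replicate 2 (0.071; range 0.0014 to 0.086).

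In all, 18 of 27 lists were called with a preset correlation of 0.01, 6 higher and 12 lower. With an estimated correlation 0 were called, and 0 had an unadjusted p under 0.05. That test also missed the shifted list in the 1 simulated data set. Genes were independent there, so the miss does not settle how to read the lack of calls here. By fry, which asks whether a list's genes move on balance one way, 13 lists passed, 11 of them among the 18, and the other 2 were the MEIS and PBX cofactors and the dendritic cell markers. The 7 called lists that did not pass by fry were the primary granule genes (adjusted p = 0.57), secondary and tertiary granule genes (0.17), interferon-stimulated genes (0.15), receptors for growth factors and cytokines (0.077), NADPH oxidase genes (0.076), cell cycle inhibitors and apoptosis regulators (0.072) and homing and adhesion genes (0.056).

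**Figure D3:**
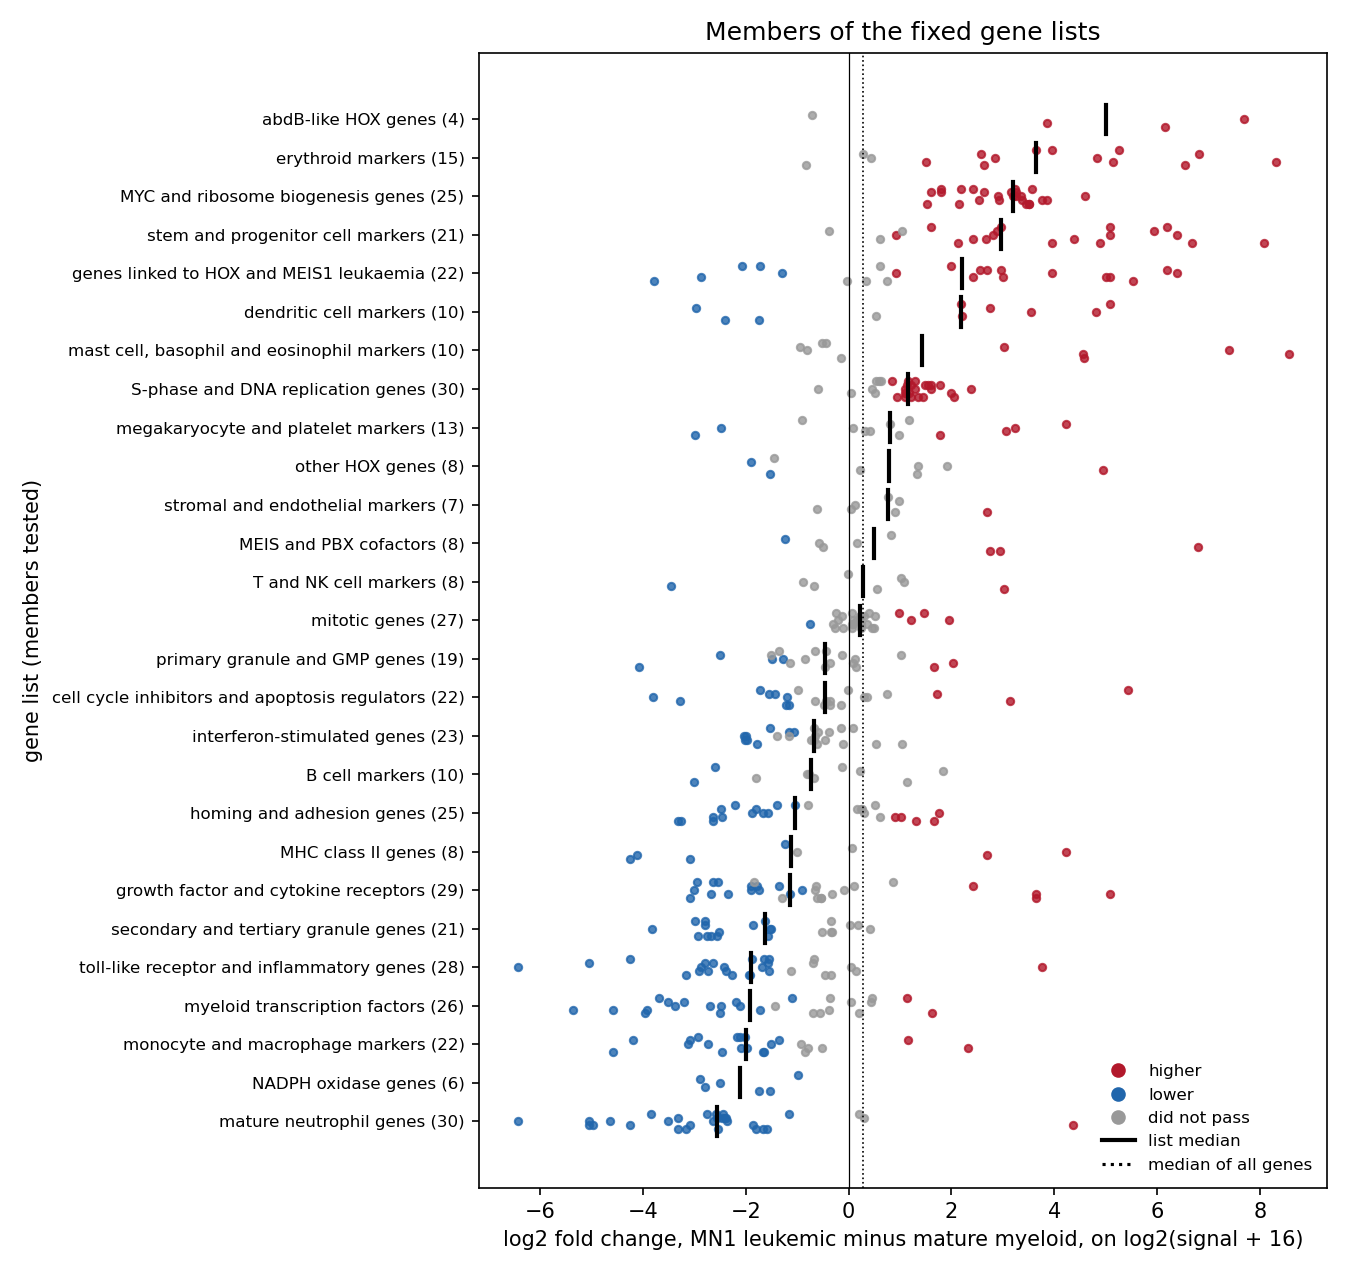
Log2 fold change (leukemic minus mature, log2(signal + 16) scale) of every tested member of the 27 fixed gene lists, 1 point per gene, with higher genes in red, lower genes in blue, genes that did not pass in grey, a black bar at each list's median and a dotted line at the median of all genes, 0.28. The medians run from -2.56 for mature neutrophil genes to 5.00 for abdB-like HOX genes, and a list such as the dendritic cell markers holds members on both sides.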

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

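The test of array scaling reported here was chosen after its result had been seen, and the test of 5′ loss before. Control probe sets, which the gene comparison does not use, gave different signals in the groups. The leukemic arrays had a 3′ to 5′ ratio 2.35 times that of the mature arrays for beta-actin and 1.91 times for Gapdh. Their hybridization controls, bacterial and phage transcripts added before hybridization, had 2.54 times the signal after the authors' scaling. With every array at the same median, 48.1% of changed genes were higher, in place of 63.3%. That setting itself brings the median log2 fold change to -0.05, whatever the source of the excess. It therefore cannot tell array scaling from a true excess of higher genes, and scaling stays open. Loss of 5′ signal in the leukemic RNA could lower genes too. Of the other probe sets of genes called lower, 97.0% (1860 of 1917) lay below the median of all genes, against 53.6% of all other probe sets, and 976 of the 1917 passed as lower. Probe positions along transcripts were not available, so these probe sets could lie at the same end. Of the falls, 73.5% exceeded the log2 difference of 1.23 in the beta-actin ratio, but such a loss can differ between transcripts, so it stays open. A true difference in RNA makeup between leukemic and mature cells was not tested and stays open.

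Probe sets that name no single gene carried differences as well. Of the 4617 kept, 651 were higher and 628 lower in leukemic marrow when all kept probe sets were tested.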

How the results depend on the processing

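Scaling to the hybridization controls and the settings without X and Y genes or granulocyte lists were chosen after the data were seen. The count of 5375 changed genes stayed within 1.5 times under all settings but 3. It was 9428 with each probe set tested, where more features were tested, and leaving out an array gave 2575 to 5441, low without a leukemic array. The HOX complex count of 7 ran from 5 to 8 when an array was left out and was 10 with hybridization controls, where a common offset between replicates made p values not comparable, and 15 to 18 lists were called when an array was left out. With an estimated correlation 0 of 27 lists were called, by a test that also missed the shift in the 1 simulated data set of independent genes. By fry 13 of 27 lists passed, 11 of them among the 18 called in the main analysis. With a replicate block 5562 genes changed (same-numbered arrays correlated at -0.03 in their deviations), 7 HOX complex genes and 18 lists passed, and the call of Hoxb1 alone was lost among named genes. The results that reversed had not passed, except Ighm and Ect2, and the cause was not tested. The other HOX gene test turned with medians of 0.78 (fry, replicate block), 0.45 (same median) and -0.26 (hybridization controls). It also turned with 0.74 (without leukemic replicate 1) and 1.06 (without mature replicate 2). That of T and NK markers turned with 0.27 (fry, no variance trend), -0.054 (same median) and -0.77 (hybridization controls). That of mitotic genes turned with -0.11 (same median), -1.12 (hybridization controls) and 0.12 (without mature replicate 2). Their median ran from 0.11 to 0.32 with an array left out, and leaving out any other array did not turn the test. The test of stromal markers turned with 0.038 (no probe sets matching several transcripts) and -0.24 (without mature replicate 1). Their median ran from -0.24 to 1.44 with an array left out, and leaving out any other array did not turn the test. Meis3 was -0.12 (quantile), -0.16 (same median), -0.96 (hybridization controls) and -0.15 to 0.48 (an array left out). Pknox2 was 0.014 (mean of probe sets), Ighm 0.23 (no probe sets matching several transcripts), Pbx3 -0.43 and Ect2 -0.11 (hybridization controls). Signals near the filter of 47.6 limit the dim HOX genes.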

Other observations

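Gene families, chosen after the data had been seen and taken by symbol, were also examined. Some share members with the fixed lists or the named genes, such as Ddx21 and Ddx4 among the DEAD-box helicases and Clec1b among the C-type lectins. Symbols also took the kinase gene Eif2ak4 and the Y-linked Eif2s3y, bright in mature replicate 2 alone, into the translation initiation factors. All 8 subunits of the CCT chaperonin, which folds actin and tubulin, rose (median 1.78, camera adjusted p = 2.8e-04; adjusted p = 0.57 with an estimated correlation). Of 35 aminoacyl-tRNA synthetases, which load amino acids onto tRNA, 30 rose and none fell (median 1.92, 4.8e-08; adjusted p = 0.57 with an estimated correlation). Cytosolic ribosomal proteins rose in 32 and fell in 1 of 46 cases (median 1.19, 1.4e-05; adjusted p = 0.57 with an estimated correlation), and their median was -0.14 with arrays scaled to the hybridization controls. Under that scaling, where all genes had a median of -0.95, mitochondrial ribosomal proteins (40 higher, 1 lower of 73, median 0.90, 1.4e-05) were at -0.41 and translation initiation factors (26 higher, 2 lower of 46, median 0.94, 0.0071) at -0.39. DEAD-box helicases (18 higher, 1 lower of 33, median 0.99, 8.5e-04) were at -0.25 and proteasome subunits (16 of 38 higher, none lower, median 0.59, 0.021) at -0.73. The adjusted p with an estimated correlation was 0.48 for DEAD-box helicases, 0.58 for proteasome subunits and 0.57 for the other 2 families.

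Subunits of the vacuolar ATPase, which acidifies lysosomes, fell in 8 of 18 cases (median -0.68, 7.3e-04; adjusted p = 0.48 with an estimated correlation), and C-type lectins, many of them receptors of myeloid cells, fell in 10 and rose in 1 of 17 (median -2.07, 1.3e-04; adjusted p = 0.57 with an estimated correlation). Cathepsins (6 lower, 3 higher of 13, median -0.99, 0.090), complex I subunits (11 higher, 3 lower of 33, median 0.25, -0.07 with every array at the same median, 0.34) and cholesterol synthesis enzymes (3 higher, 5 lower of 17, median -0.03, 0.23) were not called. The 18S ribosomal RNA probe sets read 9631 and 7947 in the leukemic and 24187 and 19078 in the mature arrays.

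Of the tests that follow, those of overall scaling and of 3′ bias between the leukemic arrays were chosen after the result had been seen. Granulocyte genes were higher in leukemic replicate 1 than in replicate 2. The median difference over all tested genes was -0.0056. Both arrays had been scaled to 1 target before deposit, which holds this median near 0, so it does not test overall scaling. The hybridization controls were brighter in replicate 1 by 0.41 on the log2 scale. In the deposited values the granulocyte genes still moved apart from the other genes. The beta-actin 3′ to 5′ ratios differed by 0.082 on the log2 scale, against about 1 for the granulocyte lists. A larger share of granulocytes in replicate 1 may account for the higher granulocyte genes. Among 208 bright genes outside the lists that were at least 4-fold lower in leukemic marrow, 205 were higher in replicate 1, by a median of 0.90, while genes at least 4-fold higher in leukemic marrow had a median of -0.19. Whether these cells were leukemic or residual normal granulocytes was not tested.

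Erythroid genes were higher in leukemic marrow, and late erythroid cells could have brought them. The median of 12 late genes was 0.38, with 3 higher and 1 lower, against 5.14 for 9 early genes (both lists were written before this test). The bound set for this test took no account of late genes that were already bright in mature marrow, such as Alas2, at 1354 and 3152 in the leukemic and 6164 and 2176 in the mature arrays, where a share of late cells would be hidden. Among the 5 late genes with a mean mature signal under 1000, a cut chosen after the values were seen, the median was 2.58, and Hemgn (4.77), Slc4a1 (2.64) and Epb42 (2.58) were higher. Globin probe sets were bright in every array, at 33493 or more for beta-globin, and say little. Late erythroid cells, early erythroid progenitors and erythroid gene activity within leukemic cells all stay open. The choice of the mature cells by Gr1 and CD11b may add to the contrast.

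Mast cell genes such as Cpa3 and Ms4a2 rose in leukemic marrow, and mature mast cells or basophils could be a source. The median leukemic signal of 14 effector genes of these cells was 47.5, below the bound set before the test, but probe sets of different genes differ in response, so that level decides nothing. Of the 14, 6 had at least 4 times the mature signal, a contrast chosen after the values were seen. These were Mcpt8 (3077 against 126), Cma1 (785 against 17.1), Mcpt2 (356 against 9.81), Cyp11a1 (190 against 5.43), Mcpt1 (81.7 against 20.2) and Tph1 (51.9 against 5.13), while Hdc read 8155 against 11726. Apart from Mcpt8, the mature signals of these genes lay below the filter of 47.6, so their ratios, taken without a pseudocount, are uncertain. Hdc lay above it in both groups. Mature cells, early mast cell or basophil progenitors and activity of these genes in leukemic cells all stay open. Here too the choice of the mature myeloid cells by Gr1 and CD11b may add to the contrast.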
